A study of Mus musculus with 7 samples.

How the data were processed

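RNA from scraped colon epithelium was sequenced as 7 libraries, each 1 pool of RNA from 3 female mice. The mice were hCYP1A animals, C57BL/6 mice in which the human CYP1A genes stand in for the mouse ones. They were 6 weeks old. Of the 7 libraries, 1 came from untreated controls, 3 from mice given 1.5% DSS (dextran sulfate sodium, which causes colitis) in drinking water for 5 days, and 3 from mice given 2 oral doses of 100 mg/kg PhIP, a heterocyclic amine formed when meat is cooked, 4 days apart and before the same DSS course. Treated mice were killed 1, 3 or 7 days after DSS ended, so each arm and day had 1 library. Groups and days were taken from the sample labels. The names of the deposited tables carry other day codes, 3, 7 and 17 for the label days 1, 3 and 7 in both arms and 7 for the control. They order the treated libraries as the labels do, and what they count from is not given in the sources used here.

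Per the file headers, each deposited table gives the count of uniquely mapped reads per gene, a gene length and the RPKM. The read counts were whole numbers that summed to the library total stated in the header. The deposited RPKM values equalled the reads divided by gene length and library total, with a largest relative deviation of 7.8e-14, so they carry no normalization beyond depth and length. The submitters' processing notes name the mm10 genome build and FastQC. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Genes with no read are missing from a library's table and were entered as 0 reads. Across the libraries 18036 genes were listed at least once and 14089 were listed in all 7. Gene identifiers were matched to symbols and positions in a RefSeq gene table of GRCm38.p6, which gave a symbol to 17983 and none to 53, and the latter held at most 0.178% of the reads of a library. For 56 genes the stated length differed between libraries, which affects their RPKM but not their reads. Genes with near-identical copies (Clca4b, Lyz1, Ang4, Hspa1a, the class II genes), and genes that overlap another or have an antisense partner, are uncertain to the extent that unique reads could not be assigned to one of them. Small RNA genes such as Mir196b can also take reads from longer transcripts over the same place.

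The control library held 7664276 unique reads, the DSS libraries 8730073, 8781886 and 8256557 on days 1, 3 and 7, and the PhIP/DSS libraries 8536432, 8424388 and 8401252. A gene with 0 reads in the control library may still be present at up to 3 reads. Folds against 0 reads were computed against that floor of 3 reads over the group and are given as lower bounds. With 1 to 3 reads the ratio of depth-scaled reads is given with an exact 95% Poisson-based interval. Floors and intervals cover counting error only.

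P-values of single genes here measure only the spread between these pooled libraries. Those of gene lists compare the genes of a list with the other genes, so they also depend on the number of genes and the spread between them. Counts of 12061 genes with at least 1 RPKM in at least 2 libraries were fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalization, quasi-likelihood test, Benjamini-Hochberg adjustment, call at an adjusted p under 0.05). One fit held all 7 libraries, with a level for the control and for each day plus 1 term for PhIP. No condition had replicate libraries, so the spread came from how much the difference between the arms varied across days, with 2 residual degrees of freedom. The control library was assumed to vary like the treated ones. The common dispersion was 0.0563, a biological coefficient of variation of 23.7%. A gene whose arm difference swung between days had a wide standard error in every comparison for this reason. The 5 tested comparisons were each day against the control (the mean of both arms), day 7 against day 1, and PhIP/DSS against DSS over the 3 days. The 3 comparisons with the control share its 1 library, so its chance deviations enter all of them.

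Before the data were examined, 34 gene lists were fixed (inflammatory and interferon genes, markers of epithelial lineages and of other cell types, proliferation, stress responses, metabolism and transport), with the main design and the other settings named here except those said to be added later. Some genes stand in more than 1 list, among them S100a8, S100a9, Nos2, Il1rn, Mmp8, Mmp9, Slc26a3 and Slc9a3. Lists were tested with camera (limma 3.58.1, two-sided, inter-gene correlation preset at 0.01), which asks whether a list's genes rank above or below the other genes, and adjusted over all 170 tests. Of these, 77 passed with the preset correlation and 0 passed with an estimated one. With a preset correlation the p-values treat genes within a list as nearly independent. The list tests with no filter, with no PhIP term, with no day block and with libraries left out were added after the data had been examined. A list's median is over fitted log2 fold changes, and it is also given with members that had 0 reads in a group set to their bound where that moves it.

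Genes were named by a rule fixed beforehand. Where no gene passed, it took up to 5 genes per direction with the largest mean log2 difference, the same sign in every pair of libraries and a mean of at least 5 RPKM. It also took up to 4 members with the largest change from each list described, 10 genes set in advance (Cyp1a1, Cyp1a2, Lcn2, Il1b, Slc26a3, Muc2, Lgr5, Mki67, Cdkn1a, Nqo1), and for each single day up to 5 genes per direction with at least 5 RPKM in the higher library. Loci with only a provisional name were not named. Which lists to describe with examples, and how many examples, was chosen after the results were seen. Cell types that could carry the interferon and MHC class II difference were weighed by their marker lists, and the bound that would exclude one was changed with the quartiles known. It was first an upper quartile below 0 on a day, then one below the lower quartiles of the interferon and MHC class II lists, and last, as used, one below 0 on at least 2 days, since 1 library per arm excludes nothing. The second had argued against macrophages and monocytes on days 3 and 7, and the first and last leave them undecided. The first would have argued against B and plasma cells on day 3, where their upper quartile was -0.0295, and the last leaves them undecided. Differences between the arms on a day were also computed as log2 ratios of depth-scaled reads with 0.5 added, for members with at least 10 reads, after the data had been examined. Adipocyte genes were noticed in the data and are described on that footing.

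Single libraries were compared without a test, as differences of log2(RPKM + 1), which understates the change of low genes, and genes were counted at a 2-fold difference. A list's median was also placed among 10000 random lists of its size matched on mean expression. Principal components were computed from log2 CPM of the tested genes. The gene tests were repeated with DESeq2 1.42.0, limma on log2(RPKM + 1) and log2(RPKM + 0.1), median-ratio size factors, no filter, a mean of at least 5 RPKM, no PhIP term, no day block, the treated libraries alone, a day left out and each treated library left out in turn. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.

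The fits were tested on simulated data with 12061 genes and 50 changed genes per fold size. The edgeR fit called 10% of 2-fold, 70% of 4-fold, 96% of 8-fold and 100% of 16-fold changes for day 1 against the control, with 5 false calls. For PhIP/DSS against DSS it called 48% of 2-fold and 100% of 4-fold changes, with 6 false calls. The simulation gave all genes a common spread, so its call rates hold only where that spread applies. It does not cover genes whose spread differs, among them those whose arm difference swings between days. In the real data edgeR called 0 genes for day 1 against the control. Clca4b, with a log2 fold change of 6.38 (SE 0.38) there, had an edgeR adjusted p of 0.071. The call rates therefore cannot be read as the power of the real fit.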

Results

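Gene expression in the colon epithelium was measured by RNA sequencing in 7 libraries, 1 per condition. They were an untreated control, DSS at 1, 3 and 7 days after the end of DSS, and PhIP/DSS at the same days. The labels give normal pathology for the control, colitis for days 1 and 3, and partial colitis for day 7. Sequencing depth was similar across libraries, and between 15849 and 16134 genes had at least 1 unique read in each. The most abundant gene in each was Lypd8, an anti-bacterial glycoprotein gene of the colonocyte surface, with between 1.08% and 2.17% of the reads. Each value of a single library is 1 measurement of 3 pooled mice and has no replicate. Mouse Cyp1a1 and Cyp1a2, which these mice lack, had 0 reads in all 7 libraries, and the human CYP1A genes that replace them are not among the genes of the tables.

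The first principal component of the libraries, with 57.9% of the variance, ran from the control at -70.97 to PhIP/DSS day 1 at 55.9. Between them lay PhIP/DSS day 3 at -19.25, PhIP/DSS day 7 at -6.79, DSS day 1 at -3.17, DSS day 7 at 15.7 and DSS day 3 at 28.6. The second component, with 17.6%, followed the day, from 25.5 and 23.9 in the 2 day 1 libraries to -26.35 and -29.07 in the 2 day 7 libraries. The DSS arm thus lay farthest from the control on day 3, and the PhIP/DSS arm on day 1.

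**Figure D1:**
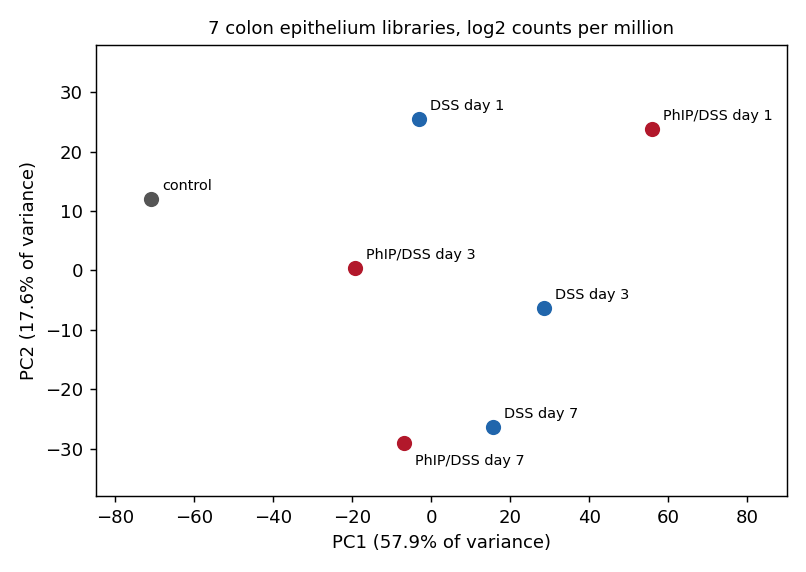
Principal components of log2 CPM, 1 point per library (grey, control; blue, DSS; red, PhIP/DSS). The horizontal axis (57.9% of variance) runs from the control to PhIP/DSS day 1, and the vertical axis (17.6%) orders the treated libraries by day.

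The comparison of day 1 with the control addressed the epithelium just after DSS was withdrawn. Genes of DNA replication and mitosis rose as a group, with all 20 of the proliferation list higher and a median log2 fold change of 0.98 (camera adjusted p = 6.09e-10). Of them 17 passed when adjusted over the list alone and 0 passed over all genes. Rrm2, a subunit of ribonucleotide reductase, stood at 4.39 RPKM in the control, 25.5 in DSS and 37.6 in PhIP/DSS (log2 fold change 2.83, SE 0.37, edgeR adjusted p = 0.071). The replication helicase genes Mcm3 and Mcm5 had log2 fold changes of 1.47 (SE 0.20) and 1.38 (SE 0.21), whereas Mki67 was at 36.8 RPKM in the control, 43.4 in DSS and 32.4 in PhIP/DSS. The unfolded protein response list rose with 12 of 13 members higher (median 1.12, adjusted p = 8.95e-07), led by Creld2 (1.56) and Sdf2l1 (1.52), and 10 members passed when adjusted over the list alone. NRF2 targets, genes of the oxidative stress response, rose with 16 of 21 higher (median 0.92, adjusted p = 2.26e-05), and Nqo1 went from 10.7 RPKM to 22.1 in DSS and 28.7 in PhIP/DSS. The adjusted p with an estimated correlation was 0.687 for each of these 3 lists.

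Goblet, tuft and crypt stem cell markers and transport genes fell on day 1. Absorptive colonocyte markers (8 of 17 higher, median -0.07, adjusted p = 0.748) and enteroendocrine markers (7 of 12 higher, median 0.01, adjusted p = 0.887) did not pass. Of 15 ion and water transport genes 13 were lower (median -0.97, adjusted p = 1.10e-05) and 6 of them passed when adjusted over the list alone. Slc4a4, a sodium bicarbonate cotransporter, fitted at -2.35 (SE 0.30), the chloride channel gene Best2 at -1.87 (SE 0.35) and the proton pump gene Atp12a at -1.80 (SE 0.72). Slc26a3, the chloride/bicarbonate exchanger of surface colonocytes, stood at 469.8 RPKM in the control and at 175 and 139 in DSS and PhIP/DSS. Goblet cell markers fell with 11 of 13 lower (median -0.66, adjusted p = 0.000577), 8 of them past the threshold when adjusted over the list alone. Clca1 was at 2374 RPKM in the control against 765 and 564, Fcgbp at 824 against 325 and 225, and the mucin gene Muc2 at 1180 against 892 and 477. The lowest fold of the list was that of Mptx1, a pentraxin gene, at 1804 RPKM against 6.13 and 5.11 (-8.36, SE 1.28, adjusted p = 0.071). Tuft cell markers were lower in 5 of 6 (median -1.57, adjusted p = 0.0181), with Trpm5 at -2.58 and Ltc4s at -2.07, and crypt stem cell and Wnt target genes in 9 of 11 (median -0.72, adjusted p = 0.0145), with Lgr5 at 2.71 RPKM against 1.75 and 1.02. All 4 lists that fell had an adjusted p of 0.687 with an estimated correlation. Without the DSS day 1 library the tuft cell markers no longer passed (adjusted p = 0.458). The crypt stem cell and Wnt target genes did not pass without PhIP/DSS day 1 (median -0.48, adjusted p = 0.0797) or without the filter on low values (adjusted p = 0.140).

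Inflammatory and wound-associated lists rose on day 1, with most members of each higher in PhIP/DSS than in DSS. The PhIP/DSS library also held transcripts abundant in fat tissue, with Cfd at 55.2 RPKM against 0.124 in DSS and 8.45 in the control. All 19 acute inflammatory mediators were higher (median 5.71, or 4.78 with genes lacking control reads at their bound, adjusted p = 1.14e-05). Il1b was at 1.28 RPKM in the control, 17.7 in DSS and 263 in PhIP/DSS, and Cxcl3 and Osm, with 0 control reads, were at least 6.14-fold and 1.46-fold higher in DSS and at least 91.0-fold and 45.5-fold higher in PhIP/DSS. The antimicrobial response list had 14 of 18 members higher (median 3.19, adjusted p = 0.000841). Saa3, an acute phase gene, went from 1.72 RPKM to 55.2 and 965, Reg3b, a C-type lectin, from 1.72 to 40.0 and 463, and Lcn2, which binds siderophores, from 0.765 to 11.3 and 249.5. All 15 neutrophil markers were higher (median 9.04, or 5.54 at the bounds, adjusted p = 0.00303), with Clec4e at least 12.3-fold higher in DSS and 266-fold in PhIP/DSS, and Retnlg at least 4.39-fold and 97.9-fold. Of these 15 markers 6 had 0 control reads, as had 3 of the 19 mediators. Genes under 1 RPKM in the control passed the filter on low values only through treated libraries. The direction of such genes is therefore partly set by the filter, here and on days 3 and 7. S100a9, with 3 control reads, was at 16.4 RPKM in DSS, a ratio of 20.5 (interval 6.73 to 102), and at 426 in PhIP/DSS, a ratio of 532 (182 to 2580). S100a8, with 1, was at 11.7 and 250 RPKM, ratios of 35.1 (5.95 to 1421) and 752 (134.5 to 29720). Both genes stand in the antimicrobial and in the neutrophil list. All 13 macrophage and monocyte markers (median 2.35, adjusted p = 0.000334) and 13 of 15 fibroblast and matrix markers (median 3.09, adjusted p = 0.000541) were also higher. With an estimated correlation the adjusted p was 0.687 for the antimicrobial list, 0.773 for neutrophil markers and 0.724 for the other 3. Without the PhIP/DSS day 1 library the neutrophil markers had a median of 2.52 and no longer passed (adjusted p = 0.0721), and the medians were 2.47 for acute inflammatory mediators, 1.02 for macrophage and monocyte markers and 1.31 for fibroblast and matrix markers, which passed.

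All 18 regenerative epithelium genes, a set tied to epithelial repair, were higher on day 1 (median 2.12, or 1.95 at the bounds, adjusted p = 9.72e-07), 8 of them past the threshold when adjusted over the list alone. Ly6d stood at 4.32 RPKM in the control, 227 in DSS and 196 in PhIP/DSS (5.60, SE 0.63), and Ereg, an EGF receptor ligand, at 0.315, 3.96 and 11.5. Spp1 had a ratio to its 3 control reads of 14.9 in DSS (interval 4.83 to 74.8) and 367 in PhIP/DSS (125 to 1783). All 21 interferon response genes were higher as well (median 0.86, adjusted p = 3.90e-07), with 11 past the threshold when adjusted over the list alone, among which Cxcl9 fitted at 4.24 and Cxcl10 at 3.38 with standard errors of 1.17 and 1.62. Both lists had an adjusted p of 0.687 with an estimated correlation, and without PhIP/DSS day 1 the median of regenerative epithelium genes was 1.38. Outside these lists, Clca4b, a calcium-activated chloride channel regulator gene (gene 99709, GRCm38.p6 chromosome 3, 144910921 to 144932529), was at 3.13 RPKM in the control library against 288 and 240, a log2 fold change of 6.38 (SE 0.38, adjusted p = 0.071). Among the genes with the lowest folds besides Mptx1 (gene 66289, chromosome 1, 174330518 to 174332877) were Slc37a2 at 97.3 RPKM against 4.46 and 1.53, Tppp3 at 84.1 against 3.08 and 5.86, Tppp at 40.2 against 2.35 and 1.67, and the calcium-binding protein gene S100g at 46.8 against 3.10 and 1.22.

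For single genes, edgeR called 0 of 12061 on day 1 at an adjusted p under 0.05, with a smallest adjusted p of 0.071. An unadjusted p under 0.05 was reached by 3932, and DESeq2 called 1243, limma on log2(RPKM + 1) 0 and limma on log2(RPKM + 0.1) 6. The 2 day 1 libraries decided this count: 4280 genes were called without DSS day 1 and 1495 without PhIP/DSS day 1, since the spread then came from days 3 and 7 alone. Cdkn1a, the p53 target p21, was at 252 RPKM in the control against 231 and 259.

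On day 3 the inflammatory, antimicrobial and repair-associated lists rose against the control. In PhIP/DSS 18 of 19 acute inflammatory mediators, 15 of 15 neutrophil markers and 13 of 18 regenerative epithelium genes were lower than in DSS, against 9 of 18 of the antimicrobial epithelial response. All 19 acute inflammatory mediators (median 4.395, or 3.89 at the bounds, adjusted p = 3.09e-06), 14 of 18 antimicrobial genes (median 3.78, adjusted p = 6.22e-07), all 15 neutrophil markers (median 7.62, or 5.44 at the bounds, adjusted p = 0.000153) and all 18 regenerative genes (median 1.43, adjusted p = 1.76e-07) were higher. Members under 1 RPKM in the control passed the filter on low values only through treated libraries. S100a9 was at 583 RPKM in DSS and 14.4 in PhIP/DSS against 0.802 in the control, ratios of 726 (interval 248 to 3525) and 17.9 (5.83 to 89.2). S100a8, with 1 control read, had ratios of 1251 (224 to 49430) and 33.7 (5.68 to 1365). Lcn2 was at 253 and 4.45 RPKM against 0.765, Il1b at 127 and 7.51 against 1.28, and Lrg1 at 113.4 and 24.5, ratios to its 2 control reads of 596 (165 to 4927) and 129 (35.3 to 1068). Nos2, the inducible nitric oxide synthase gene, was nearer between the arms, at 84.8 and 60.4 RPKM against 1.41 (log2 fold change 5.74, SE 0.95), and Clca4b at 643 and 426 against 3.13 (7.42, SE 0.39, adjusted p = 0.0625). All 21 interferon genes were higher (median 1.12, adjusted p = 4.81e-11), 12 of them past the threshold when adjusted over the list alone, with Cxcl9 at 4.07 (SE 1.17) and Cxcl10 at 2.62 (SE 1.57). Macrophage and monocyte markers rose in 13 of 13 (median 1.94, adjusted p = 0.000282) and fibroblast and matrix markers in 13 of 15 (median 2.41, adjusted p = 0.000337). Proliferation genes rose here too, with 18 of 20 higher and a median of 0.45 (adjusted p = 0.000337). The adjusted p with an estimated correlation was 0.724 for the mediators and the neutrophil, macrophage and fibroblast markers, 0.721 for proliferation and 0.687 for the antimicrobial, regenerative and interferon lists. Without DSS day 3 the medians were 1.62 for acute inflammatory mediators, 1.90 for the antimicrobial epithelial response, 3.04 for neutrophil markers, 0.98 for macrophage and monocyte markers, 1.57 for fibroblast and matrix markers and 0.23 for proliferation, and all of these passed. Without PhIP/DSS day 3 the median of macrophage and monocyte markers was 3.32.

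Transport, tuft cell and crypt stem cell genes stayed low on day 3, while goblet cell markers did not pass (median 0.44, adjusted p = 0.188). Tuft cell markers were lower in 4 of 6 (median -1.34, adjusted p = 0.0102), though not past the threshold without PhIP/DSS day 3 (median -0.86, adjusted p = 0.0750). Crypt stem cell and Wnt target genes were lower in 8 of 11 (median -0.52, adjusted p = 0.0114), though not past it without the filter on low values (adjusted p = 0.145). Ion and water transport genes were lower in 12 of 15 (median -0.58, adjusted p = 0.000252), with Slc4a4 at -1.90 (SE 0.29) and Slc26a3 at -1.57 (SE 0.25). The list of aryl hydrocarbon receptor targets and PhIP-metabolizing enzymes fell, with 8 of 13 lower and a median of -0.41 (adjusted p = 0.0153). Its lowest folds were those of the sulfotransferase gene Sult1a1, at 184 RPKM in the control against 39.1 in DSS and 53.4 in PhIP/DSS, and of the cytochrome P450 gene Cyp2s1, at 129 against 34.8 and 51.2. These 4 lists had an adjusted p of 0.687 on an estimated correlation, and the AhR targets and PhIP metabolism list did not pass without the filter on low values (adjusted p = 0.145) and had a median of -0.08 without DSS day 3. Mptx1 remained low at 1.70 RPKM in DSS but was at 59.1 in PhIP/DSS, against 1804 in the control, and the same order held for Slc37a2 (1.74 and 11.8), S100g (0.474 and 13.8) and Tppp3 (3.83 and 16.3). Ang4, an angiogenin with antibacterial activity, fitted at -3.32 (SE 0.45), opposite to most of the antimicrobial list. Muc2 was at 1238 and 807 RPKM against 1180, Lgr5 at 2.54 and 1.97 against 2.71, Mki67 at 29.6 and 27.4 against 36.8, Cdkn1a at 237 and 251 against 252, and Nqo1 at 23.3 and 30.7 against 10.7. The edgeR test called 0 genes, with 2291 at an unadjusted p under 0.05, against 438 by DESeq2, 2 by limma on log2(RPKM + 1) and 16 on log2(RPKM + 0.1). Without DSS day 1 it called 2142 and without PhIP/DSS day 1 it called 2271.

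By day 7, in the recovery phase with partial colitis, interferon and antigen presentation genes rose as groups against the control. All 21 interferon response genes were higher (median 1.47, adjusted p = 1.49e-20) and 19 passed when adjusted over the list alone. Ido1, a tryptophan-degrading enzyme gene, was at 3.94 RPKM in the control, 29.1 in DSS and 41.0 in PhIP/DSS (3.17, SE 0.34, adjusted p = 0.0842), Iigp1, an interferon-inducible GTPase, at 2.57, 9.73 and 21.2 (2.51, SE 0.27), and Cxcl9 at 0.359, 7.30 and 10.9. All 9 MHC class II genes were higher (median 1.40, adjusted p = 1.08e-06), 6 of them past the threshold when adjusted over the list alone. H2-Ab1 was at 37.8 RPKM against 79.2 and 149, H2-Eb1 at 13.99 against 28.2 and 56.1, and H2-DMb2 at 0.664 against 1.39 and 3.79. Cells that carry MHC class II were measured too. Macrophage and monocyte markers were higher in 13 of 13 (median 2.27, adjusted p = 2.54e-06), while B and plasma cell markers, higher in 8 of 9, did not pass (median 0.58, adjusted p = 0.0623). In B and plasma cell markers 3 of 9 were above the control in DSS and 9 of 9 in PhIP/DSS. Fibroblast and matrix markers were higher in 14 of 15 (median 2.85, adjusted p = 2.54e-06). With an estimated correlation the adjusted p was 0.721 for fibroblast and matrix markers and 0.687 for the other 3 lists that passed.

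Repair-associated genes also rose on day 7, with all 18 regenerative genes higher (median 1.88, adjusted p = 4.81e-11) and Ly6d at 138 and 156 RPKM against 4.32. The 3 squamous epithelium markers that passed the filter on low values were higher (median 3.26, or 2.79 at the bounds, adjusted p = 0.00514), with the keratin gene Krt14 at 0.854 RPKM in the control against 10.3 and 5.46, and Krt13, which had 0 control reads, at least 12.4-fold higher in DSS and 1.52-fold in PhIP/DSS. Both genes were under 1 RPKM in the control and passed the filter only through treated libraries, so their direction is partly set by it. Mmp7, the matrilysin gene, was at 0.297 RPKM against 36.3 and 32.3, a ratio of 115.3 to its 2 control reads (31.7 to 954). Clca4b was at 509 and 591 RPKM (7.49, SE 0.40, adjusted p = 0.0593). All 15 neutrophil markers were still higher (median 6.81, or 4.55 at the bounds, adjusted p = 2.26e-05), with ratios for S100a9 of 294 in DSS (100 to 1428) and 39.5 in PhIP/DSS (13.2 to 194), and for S100a8 of 464 (82.9 to 18370) and 67.5 (11.8 to 2702). As with Krt13 and Krt14, markers under 1 RPKM in the control passed the filter only through treated libraries. Absorptive colonocyte markers fell, with 13 of 17 lower and a median of -0.60 (adjusted p = 0.0102). Slc26a3 was at 110 and 158 RPKM against 469.8, and Cyp2c55 at 56.1 and 23.5 against 131.5. Oxidative phosphorylation genes were lower in 15 of 19 (median -0.22, adjusted p = 0.0101). The p on an estimated correlation, adjusted, was 0.724 for neutrophil markers and 0.687 for the other 4 lists. The absorptive colonocyte markers did not pass without PhIP/DSS day 7 (median -0.40, adjusted p = 0.188), nor oxidative phosphorylation without DSS day 1 (adjusted p = 0.0834) or PhIP/DSS day 1 (adjusted p = 0.0708). Without the filter on low values the adjusted p was 0.134 for absorptive colonocyte markers and 0.104 for squamous epithelium markers.

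The proliferation list (median 0.18, adjusted p = 0.362) and tuft cell markers (4 of 6 lower, median -0.98, adjusted p = 0.0996) did not pass on day 7. Crypt stem cell and Wnt target genes were lower in 9 of 11 (median -0.41, adjusted p = 0.00946, and adjusted p = 0.687 with an estimated correlation). They did not pass without DSS day 7 (adjusted p = 0.0656) or without the filter on low values (median -0.01, adjusted p = 0.574). Ion and water transport genes were still lower in 12 of 15 (median -0.70, adjusted p = 7.09e-06, and adjusted p = 0.687 with an estimated correlation). Mptx1 was still at 13.3 RPKM in DSS and 132 in PhIP/DSS against 1804, Slc37a2 at 4.39 and 22.8 against 97.3, and the peptidase gene Naaladl1 at 3.73 and 6.70 against 37.4. Cfd and Car3, both abundant in fat tissue, were at 8.45 and 7.64 RPKM in the control against at most 0.129 in the day 7 libraries. Lcn2 was at 46.9 and 16.7 RPKM against 0.765, Il1b at 101 and 36.1 against 1.28, Muc2 at 939 and 548 against 1180, Lgr5 at 1.44 and 3.06 against 2.71, Mki67 at 26.2 and 28.7 against 36.8, Cdkn1a at 284 and 226 against 252, and Nqo1 at 24.7 and 21.01 against 10.7. For single genes edgeR called 0, with 2076 at an unadjusted p under 0.05, while DESeq2 called 459, limma on log2(RPKM + 1) 2 and on log2(RPKM + 0.1) 42, and edgeR without a filter 29. Without DSS day 1 the count was 1896, and without PhIP/DSS day 1 it was 2010.

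**Figure D2:**
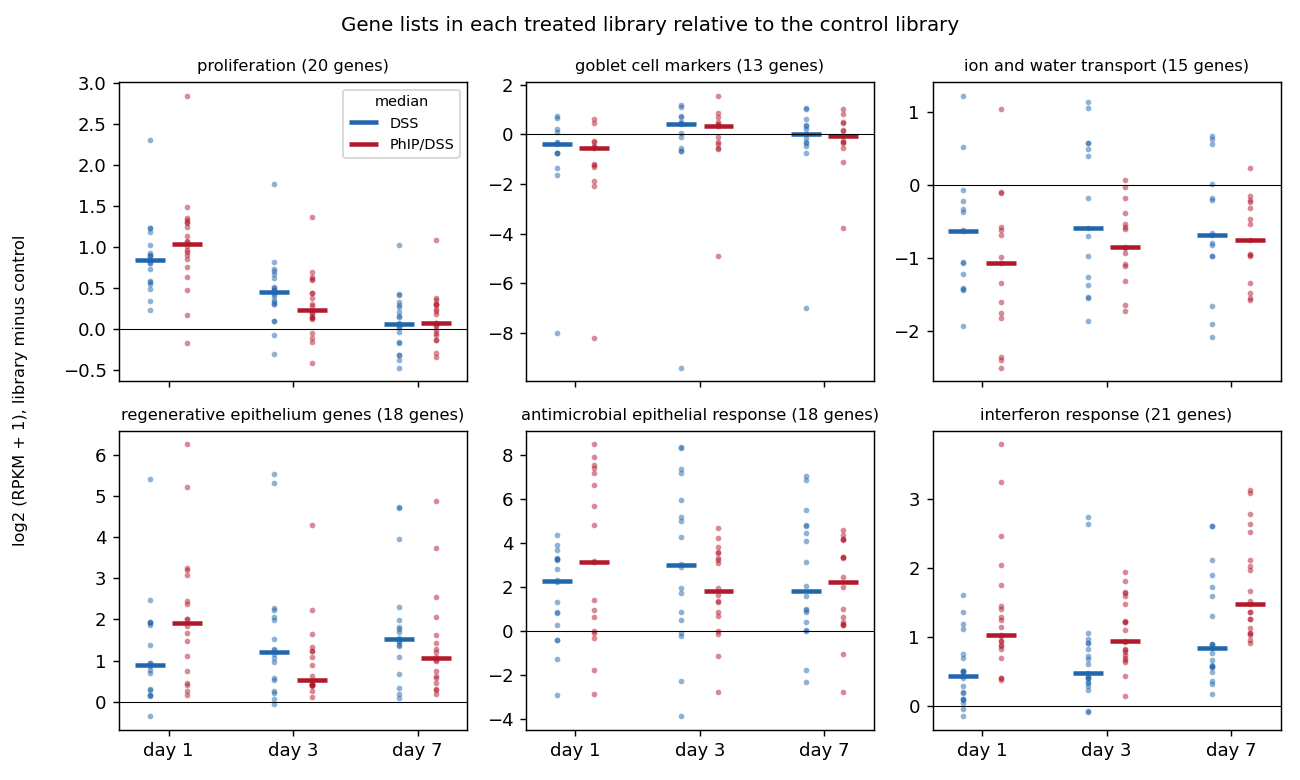
Differences in log2(RPKM + 1) between each treated library and the control library, 1 point per gene and a bar at the median of each list (blue, DSS; red, PhIP/DSS), by day after DSS. Proliferation medians go from 0.84 in DSS and 1.03 in PhIP/DSS on day 1 to 0.06 and 0.07 on day 7, while interferon medians are highest on day 7, at 0.84 and 1.47.

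Day 7 against day 1 compared recovery with the end of DSS, fitted as a change shared by both arms. The same sign in both arms was asked only of genes named for the largest differences. List counts and the genes set in advance did not require it. All 20 proliferation genes fell, with a median log2 fold change of -0.86 (adjusted p = 6.88e-16), and all 20 passed when adjusted over the list alone. Rrm2 had -1.59 (SE 0.26), Birc5, which encodes survivin, -1.09 (SE 0.20), and Mcm3 -1.09 (SE 0.15). All 19 oxidative phosphorylation genes were lower too (median -0.32, adjusted p = 6.22e-07), 11 of them past the threshold when adjusted over the list alone, with cytochrome c (Cycs) at -0.55 (SE 0.10) and Ndufa4 at -0.48 (SE 0.18). Goblet cell markers rose in 11 of 13 (median 0.89, adjusted p = 3.90e-07), with Clca1 from 765 to 1853 RPKM in DSS and from 564 to 1927 in PhIP/DSS, the trefoil factor gene Tff3 from 985 to 2551 and from 1131 to 2344, and Mptx1 from 6.13 to 13.3 and from 5.11 to 132. B and plasma cell markers were higher in 9 of 9 (median 1.01, adjusted p = 0.0138), with Jchain, the joining chain of polymeric immunoglobulins, from 7.81 to 34.3 RPKM in DSS and from 26.3 to 53.5 in PhIP/DSS, and Fcer2a from 0.358 to 0.378 and from 0.418 to 2.34. Their adjusted p was 0.724 with an estimated correlation, against 0.687 for the other 3 lists. The B and plasma cell call was lost without DSS day 1 (adjusted p = 0.115) and without PhIP/DSS day 7 (median 0.17, adjusted p = 0.448).

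Single genes with the highest folds from day 1 to day 7 included Clu, the clusterin gene, from 22.3 to 460 RPKM in DSS and from 48.7 to 395 in PhIP/DSS (3.71, SE 0.36, adjusted p = 0.0934). Klk15, a kallikrein gene with 0 reads in DSS day 1 and 2 in PhIP/DSS day 1, was at 19.9 and 34.5 RPKM on day 7, a ratio of 180.4 (49.6 to 1495). In the control, however, it was at 10.9 RPKM, so the ratio reflects its low level on day 1. The aspartic protease gene Ctse fitted at 3.31 (SE 0.62) and Lrmp at 3.23 (SE 0.43). Ctse was at 74.1 RPKM in the control, against 11.9 and 6.80 on day 1 and 83.8 and 106 on day 7 in DSS and PhIP/DSS. Clu and Lrmp were at 28.65 and 8.01 RPKM in the control, below both day 7 libraries. Reg3b went from 40.0 to 4.15 RPKM in DSS and from 463 to 3.14 in PhIP/DSS, Reg3g from 13.8 to 3.44 and from 145.6 to 7.07, and the heat shock gene Hspa1a from 17.9 to 1.95 and from 20.6 to 1.66 (-3.37, SE 0.21). Cfd and Car3 were at 55.2 and 35.3 RPKM in PhIP/DSS day 1 and at 0.129 and 0 in PhIP/DSS day 7. Lcn2 and Il1b had standard errors of 2.54 and 2.00 around log2 fold changes of -2.72 and -1.56. Muc2 fitted at 0.17, Slc26a3 at -0.20, Lgr5 at 0.74, Mki67 at -0.42, Cdkn1a at 0.09 and Nqo1 at -0.10, all with adjusted p above 0.1 in edgeR. The edgeR test called 0 genes, with 3172 at an unadjusted p under 0.05, against 693 by DESeq2 and 0 by both limma fits. It called 2986 without DSS day 1 and 786 without PhIP/DSS day 1.

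PhIP/DSS against DSS, matched by day, asked what PhIP before DSS added. Interferon response genes were higher in PhIP/DSS as a group, in all 21 members (median log2 fold change 0.71, adjusted p = 1.69e-39), and 17 passed when adjusted over the list alone. The GTPase genes Iigp1 (1.10, SE 0.16), Gbp6 (1.08, SE 0.34) and Gbp3 (1.00, SE 0.15) and the antiviral gene Mx2 (1.37, SE 0.39) led the list. Iigp1 was at 13.7 RPKM in PhIP/DSS against 4.98 in DSS on day 1, at 10.3 against 5.97 on day 3 and at 21.2 against 9.73 on day 7. All 9 MHC class II genes were higher (median 0.74, adjusted p = 3.66e-13), with 5 past the threshold when adjusted over the list alone, led by H2-DMb2 (1.20, SE 0.45), H2-Eb1 (0.84, SE 0.20), H2-DMb1 (0.82, SE 0.28) and H2-Aa (0.75, SE 0.19). These counts are of fitted values. By single day, 21, 19 and 20 of the 21 interferon genes were higher on days 1, 3 and 7, and 19 on all 3. Of the 9 class II genes 8, 7 and 9 were, and 7 on all 3 days. Ubd, a ubiquitin-like gene, showed the same order on each day, at 20.04 against 8.47, 13.9 against 4.45 and 54.6 against 31.7 RPKM. Both lists had an adjusted p of 0.687 with an estimated correlation, and passed in each fit with a library left out.

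Lymphocyte markers were higher in PhIP/DSS alongside these lists. All 9 T and NK cell markers were higher over the 3 days (median 0.59, adjusted p = 0.000167), with Cd8b1 at 1.25 (SE 0.53) and Cd4 at 0.96 (SE 0.60), each under 2 RPKM in every library, and so were 8 of 9 B and plasma cell markers (median 0.81, adjusted p = 9.49e-05). On single days 8, 5 and 6 of the 9 T and NK cell markers were higher on days 1, 3 and 7, and 2 of them on all 3 days. Crypt stem cell and Wnt target genes were higher in 8 of 11 (median 0.32, adjusted p = 0.000261), among them the Wnt feedback gene Axin2 (0.65, SE 0.15) and Cdca7 (0.50, SE 0.10), while Lgr5 fitted at -0.04 (SE 0.40). By single day 5, 9 and 10 of these 11 genes were higher on days 1, 3 and 7. Enteroendocrine markers were higher in 10 of 12 (median 0.22, adjusted p = 1.15e-05). Ion and water transport genes fell in 11 of 15 (median -0.27, adjusted p = 3.51e-08), with the sodium/proton exchanger gene Slc9a3 at -1.15 (SE 0.34) and the sodium channel gene Scnn1b at -1.05 (SE 0.31), and Slc26a3 at 0.01 (SE 0.18). By single day 15, 8 and 9 of these 15 genes were lower on days 1, 3 and 7. Their median differences in log2(RPKM + 1) were -0.40, -0.10 and -0.08. All 12 steroid and cholesterol synthesis genes were lower over the 3 days (median -0.20, adjusted p = 9.72e-07), with Hsd3b3 at -0.39 (SE 0.14) and Hmgcs1 at -0.25 (SE 0.14). On day 3 alone, however, 8 of the 12 were higher in PhIP/DSS, with a median difference in log2(RPKM + 1) of 0.05. These 6 lists had an adjusted p of 0.687 with an estimated correlation. Without DSS day 1 or PhIP/DSS day 1 the adjusted p was 0.0726 or 0.0797 for T and NK cell markers and 0.0964 or 0.0694 for steroid and cholesterol synthesis, and the median of ion and water transport was -0.13 in both cases. Without DSS day 3 or PhIP/DSS day 3 it was 0.0756 or 0.0739 for crypt stem cell and Wnt target genes and 0.109 or 0.157 for enteroendocrine markers, and without DSS day 7 or PhIP/DSS day 7 it was 0.134 or 0.152 for B and plasma cell markers. Crypt stem cell and Wnt target genes also missed the threshold without PhIP/DSS day 7 (adjusted p = 0.0503).

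Neutrophil markers were lower over the 3 days in 15 of 15 (median -1.02, adjusted p = 0.0145, and adjusted p = 0.830 with an estimated correlation), but the median was 0.70 without DSS day 3 and 0.69 without PhIP/DSS day 3, -0.22 without either day 7 library (adjusted p = 0.687), and -2.89 without DSS day 1 or -2.88 without PhIP/DSS day 1. Without the filter on low values they did not pass (adjusted p = 0.142). Goblet cell markers passed as lower (median -0.14, mean 0.06, adjusted p = 0.000958, and adjusted p = 0.687 with an estimated correlation), and did not pass without DSS day 1 (adjusted p = 0.475), without PhIP/DSS day 1 (adjusted p = 0.341) or without the day block (adjusted p = 0.141). Muc2 itself was lower in PhIP/DSS on each day (-0.78, SE 0.12). Lists of direct relevance to PhIP, a DNA-damaging compound once activated, did not pass. All libraries were taken after the 5 days of DSS that followed PhIP, so a brief response soon after the doses would not be seen. The aryl hydrocarbon receptor list was tested without Cyp1a1 and Cyp1a2, which these mice lack. The p53 targets had 9 of 18 higher (median 0.01, adjusted p = 0.899), DNA repair genes 10 of 19 (median 0.06, adjusted p = 0.977), and aryl hydrocarbon receptor and PhIP metabolism genes 9 of 13 (median 0.06, adjusted p = 0.641). Cdkn1a fitted at -0.05 (SE 0.13), Nqo1 at 0.17 (SE 0.16), Mki67 at -0.15 (SE 0.12), Lcn2 at -1.21 (SE 2.49) and Il1b at -0.94 (SE 1.89).

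Among genes with the same sign on all 3 days, others with the largest mean differences were Tppp3 (1.67, SE 0.26) and the lysozyme gene Lyz1 (1.31, SE 0.35) on the higher side. On the lower side were the sialyltransferase gene St3gal4 (-2.11, SE 0.74), at 7.05 against 66.6 RPKM on day 1 and 25.1 against 26.0 on day 7, B3gnt6 (-1.16, SE 0.42), Best2 (-1.04, SE 0.25) and Mir196a-1 (-1.44, SE 0.91). Mir196a-1 had only 0, 5 and 5 reads in PhIP/DSS against 8, 8 and 9 in DSS on days 1, 3 and 7, so counting error may set its sign on a single day. Cfd had 436 reads in PhIP/DSS against 1 in DSS on day 1, but 3 against 0 on day 3 and 1 against 0 on day 7, so its difference rests on PhIP/DSS day 1. No gene was called by edgeR, 0 of 12061, against 13 by DESeq2 and 0 by both limma fits. In edgeR 442 genes, or 3.665%, had an unadjusted p under 0.05, a share below the 0.05 that no difference would give. Without DSS day 1 edgeR called 282 and without PhIP/DSS day 1 it called 324, and without both it called 309.

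The 2 arms on single days, 1 library against 1 and without a test, differed in opposite directions. On day 1, 572 genes differed at least 2-fold, 520 of them higher in PhIP/DSS, and with a pseudocount of 0.1 RPKM 765 of 968 were higher. On day 3, 308 of 399 were lower in PhIP/DSS, and on day 7, 142 of 227. Across genes, which are not independent replicates, the day 1 difference correlated at -0.63 with that of day 3 and at -0.30 with that of day 7, and the day 3 and day 7 differences at 0.47. On day 1 the highest differences were those of Cfd (55.2 against 0.124 RPKM), the chemokine genes Ccl4 (156 against 3.23) and Ccl3 (128 against 3.42), the fatty acid binding protein gene Fabp4 (51.1 against 0.532) and Car3 (35.3 against 0.373). The lowest were those of St3gal4, Fabp6 (0.919 against 6.74 RPKM), and Mir196b, Mir196a-1 and Snord14c, which had 0 reads in PhIP/DSS and 10, 8 and 4 in DSS. On day 3 Saa3 (6.04 against 442 RPKM), Lcn2 (4.45 against 253), S100a9 (14.4 against 583), S100a8 (11.2 against 416) and Retnlg (1.36 against 79.3) were lower in PhIP/DSS, and Mptx1 (59.1 against 1.70), S100g (13.8 against 0.474), the calcium channel gene Trpv6 (9.19 against 0.309), Slc37a2 (11.8 against 1.74) and Cyp2c55 (60.6 against 13.2) were higher. On day 7 Retnlg (2.54 against 27.8), S100a9 (31.7 against 236), S100a8 (22.5 against 154), Ppbp (0.215 against 6.78) and Ngp (0.405 against 6.69) were lower, and Mptx1 (132 against 13.3), Slc37a2 (22.8 against 4.39), the IgM Fc receptor gene Fcmr (6.95 against 0.894), S100g (31.7 against 6.81) and the Wnt inhibitor gene Wif1 (6.26 against 0.756) were higher.

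**Figure D3:**
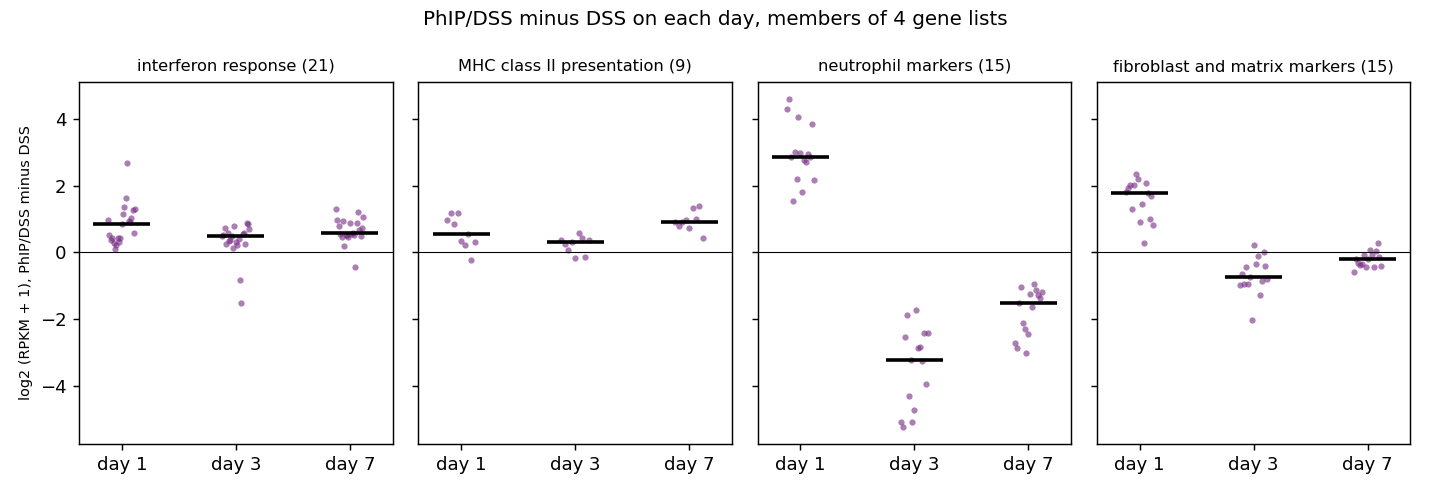
PhIP/DSS minus DSS in log2(RPKM + 1) on days 1, 3 and 7, 1 point per gene and a bar at the list median. Interferon medians are 0.84, 0.50 and 0.58 and MHC class II medians 0.54, 0.30 and 0.90, while neutrophil medians are 2.86, -3.23 and -1.51 and fibroblast medians 1.78, -0.75 and -0.20.

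Against the control, again without a test, PhIP/DSS day 1 differed most. In it 1865 genes differed at least 2-fold, 1131 higher and 734 lower, against 804 in DSS day 1. The order was the other way on day 3, with 1133 in DSS and 587 in PhIP/DSS, and on day 7 the counts were 997 and 808. Interferon genes had medians above the control of 0.43, 0.47 and 0.84 in DSS and of 1.02, 0.95 and 1.47 in PhIP/DSS on days 1, 3 and 7. Neutrophil markers had medians of 0.88, 3.98 and 2.94 in DSS and of 3.68, 0.56 and 1.44 in PhIP/DSS.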

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

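The tests of exchanged labels and of non-epithelial tissue were chosen after the differences they bear on had been seen.

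In 5 lists every member was higher in PhIP/DSS than in DSS on day 1, with a median log2 difference above 1, and the median lay below 0 on days 3 and 7. They drew attention because the arms differed in opposite directions between days. The 2 enteric glia and neuron markers had the same order with smaller medians, 0.1886, -0.06367 and -0.3475 on days 1, 3 and 7. The difference between days was not tested, since each arm had 1 library per day. On days 1, 3 and 7 the medians of PhIP/DSS minus DSS in log2(RPKM + 1) were 2.785, -1.061 and -0.9014 for acute inflammatory mediators, 2.863, -3.226 and -1.507 for neutrophil markers, and 1.428, -1.129 and -0.2771 for macrophage and monocyte markers. They were 1.775, -0.7515 and -0.1983 for fibroblast and matrix markers and 1.825, -1.7 and -1.017 for matrix metalloproteinases and inhibitors.

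An exchange of the labels of the PhIP/DSS day 1 and day 3 libraries was argued against by the proliferation list, since 20 of 20 genes were higher in the PhIP/DSS library labelled day 1 than in that labelled day 3, as they were in the DSS arm. More non-epithelial tissue of every kind alike in the PhIP/DSS day 1 scraping was argued against by 6 smooth muscle genes, 3 of them higher, whose log2 read ratios on day 1 had an upper quartile of 0.4481, below the lower quartile of the fibroblast list, 1.894, with Smtn and Tagln left out for their reads in the control, but endothelial markers were higher in 3 of 4 (median 0.9074), so more tissue of some kinds stays open. An exchange of the DSS and PhIP/DSS labels on day 1 cannot be told apart from a true difference, because the interferon median of 0.8432 on that day had the sign of the later days, which goes against an exchange, while with the 2 labels exchanged edgeR called 233 genes and 1397 had an unadjusted p under 0.05, against 0 and 442 as labelled, as an exchange or a true difference of opposite sign on day 1 would each give. The PhIP/DSS day 1 library also held fat cell transcripts, with Cfd at 55.2 RPKM against 0.124 in DSS day 1 and Adipoq at 6.94 against 0.0929, so tissue of another kind carried along stays open, and its share in these 5 lists was not tested. Also open and untested are an effect of PhIP on the course of the colitis and a difference in colitis severity between pools of 3 mice, which may each give such a pattern.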

How the results depend on the processing

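The list tests with no filter, no PhIP term, no day block and libraries left out were chosen after the data had been seen, and the other settings were not. Depth limits low genes, for which 3 reads are the floor.

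With edgeR, 0 genes were called in each of the 5 comparisons. In the order day 1, day 3 and day 7 against the control, day 7 against day 1, and PhIP/DSS against DSS, DESeq2 called 1243, 438, 459, 693 and 13 genes, and a mean of at least 5 RPKM gave 5, 3, 25, 1 and 1, with fewer genes to adjust over. The fit with no PhIP term called 1305, 27, 59 and 57 in the first 4. For the 3 comparisons with the control, no filter on low values gave 6, 3 and 29, limma on log2(RPKM + 0.1) gave 6, 16 and 42, and limma on log2(RPKM + 1) gave 0, 2 and 2. The cause was not tested except where given. Median-ratio size factors gave 0 in all 5, and PhIP/DSS against DSS with no day block, the fit that does not match the arms by day, gave 0. Leaving out each treated library in turn gave 0 to 4280 genes on day 1, 0 to 2271 on day 3, 0 to 2010 on day 7, 0 to 2986 for day 7 against day 1 and 0 to 324 for PhIP/DSS against DSS. Counts above 0 came from leaving out DSS day 1 or PhIP/DSS day 1, and leaving out both libraries of day 1 gave 309 for PhIP/DSS against DSS. By construction the spread then comes from days 3 and 7 only.

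Of 170 list tests 77 passed, against 77 with median-ratio size factors, 65 with no filter and 0 with an estimated correlation. Counts of genes with a 2-fold difference moved with the pseudocount, since it sets how far low genes can differ. For PhIP/DSS against DSS on days 1, 3 and 7 they were 968, 730 and 501 with 0.1 RPKM and 234, 145 and 56 with 5 RPKM. Against the control they were 1455 for DSS day 1, 1547 for DSS day 7, 1110 for PhIP/DSS day 3 and 1344 for PhIP/DSS day 7 with 0.1 RPKM. With 5 RPKM they were 311, 461 and 393 for DSS and 883, 215 and 299 for PhIP/DSS.

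The sign of 7 named genes turned in some settings, and the cause was not tested. With a library left out, Cdkn1a ranged from -0.2053 to 0.1028 on day 1, -0.1087 to 0.05951 on day 3, -0.204 to 0.2714 on day 7, -0.153 to 0.3225 for day 7 against day 1 and -0.1488 to 0.1123 for PhIP/DSS against DSS. Lgr5 ranged from -0.5267 to 0.01315 on day 3, -1.162 to 0.4731 on day 7, -0.1388 to 1.496 for day 7 against day 1 and -0.5806 to 0.3195 for PhIP/DSS against DSS, and Mki67 from -0.1904 to 0.2263 on day 1. For day 7 against day 1 the ranges were -0.5723 to 0.1463 for Slc26a3, -4.976 to 2.968 for Lcn2, -3.369 to 3.136 for Il1b and -0.4275 to 0.2082 for Nqo1. For PhIP/DSS against DSS they were -0.2308 to 0.1828 for Slc26a3, -3.456 to 1.472 for Lcn2 and -2.616 to 1.163 for Il1b. In that comparison Lgr5 was 0.0111 with limma on log2(RPKM + 1), 0.06112 with no day block, 0.3184 with day 1 left out and 0.161 with day 3 left out. Il1b was 0.2785 with no day block and 1.161 with day 3 left out, Lcn2 1.472 with day 3 left out, Slc26a3 -0.01435 with no day block and -0.2308 with day 7 left out, and Cdkn1a 0.1123 with day 7 left out. On day 3 Cdkn1a was 0.004886 with no filter.

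Among list tests of PhIP/DSS against DSS, the direction of the test turned with a library left out for goblet cell markers (medians from -0.1727 to -0.02421), neutrophil markers (-2.888 to 0.7026), p53 targets (-0.08763 to 0.09556), AhR targets and PhIP metabolism (-0.02552 to 0.09174), glycolysis and hypoxia (-0.3295 to -0.009248) and NRF2 targets (-0.03539 to 0.08012). It also turned for p53 targets with no filter (0.02066) and for DNA repair with no filter (-0.001006) and no day block (0.05397). The cause was not tested.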

Other observations

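The tests on neutrophils, macrophages and monocytes, T and NK cells and B and plasma cells, the count of splits for MHC class II and the reading of the day-matched splits were chosen after the differences they bear on had been seen, unlike the other counts over all splits and the test of adipocyte markers. The bound for the cell types was changed more than once with the quartiles known. A bound set by the lower quartiles of the interferon and MHC class II lists put macrophages and monocytes below both on days 3 and 7, but not on day 3 in log2 read ratios, where their upper quartile was 0.04046 against 0.01501 for MHC class II. It was given up.

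Marker lists of less abundant epithelial and immune cells differed between single libraries. Crypt stem cell and Wnt target genes had medians below the control of -0.43, -0.70 and -0.61 in DSS on days 1, 3 and 7, and of -0.60, -0.31 and -0.18 in PhIP/DSS. In enteroendocrine markers, the hormone-producing lineage, all 12 genes were higher in PhIP/DSS than in DSS on day 3 (median 0.62), against 6 on day 1 and 9 on day 7 (medians 0.01 and 0.16). B and plasma cell markers were higher in PhIP/DSS in 9 of 9 on days 1 and 7 (medians 0.56 and 1.28) and in 2 of 9 on day 3 (median -0.14). Mast cell markers, higher over the 3 days with a median of 0.69 (camera adjusted p = 0.00956, and adjusted p = 0.687 with an estimated correlation), had single-day medians of -0.07, 0.62 and 0.45. That call was lost without either library of day 3 (adjusted p = 0.138 for DSS and 0.148 for PhIP/DSS) or of day 7 (adjusted p = 0.122 and 0.131), and without the filter on low values (adjusted p = 0.102). The 3 squamous epithelium markers that passed the filter on low values were above the control in all 6 treated libraries, with medians of 1.48, 1.26 and 2.23 in DSS and 2.33, 2.06 and 1.29 in PhIP/DSS. The single-library values have no test.

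Interferon and MHC class II lists were higher in PhIP/DSS on each of the 3 days. More neutrophils were weighed as a source, though whether they would raise the MHC class II list was not tested. On days 3 and 7 all 15 neutrophil markers were lower in PhIP/DSS, with upper quartiles of -2.484 and -1.222, which argues against more neutrophils on those days. Macrophages and monocytes cannot be told apart from other sources on days 3 and 7, because their markers went both ways, 4 and 5 of 13 higher with upper quartiles of 0.03587 and 0.2122, and C1qa went from 94 reads in DSS to 169 in PhIP/DSS on day 7, nor can myeloid cells on day 1, when the lower quartile of macrophage and monocyte markers was 0.9659 in 1 library per arm. T and NK cells and B and plasma cells, whose markers had their lowest medians, 0.1304 and -0.1364, on day 3, cannot be told apart either, since B and plasma cell markers, for cells that carry MHC class II, had medians of 0.56 and 1.28 on days 1 and 7 and were lower on day 3 alone. An effect of PhIP on interferon signalling and dendritic cells, for which no list was measured, stay open and untested.

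Of the 10 splits of the 6 treated libraries into 3 and 3, the real one included, 3 gave an interferon median as large as the real 0.71, the highest other being 0.96, and 5 gave an MHC class II median as large as the real 0.74, the highest other being 0.88. With 10 splits a share under 0.05 cannot be had. The 6 splits that are not matched by day hold, with the day block, the difference between the arms on 1 day alone, the 2 at 0.96 that of day 1 and the 2 at 0.88 that of day 7. Among the 4 day-matched splits, which cannot give a share under 0.05 either, the real medians were the highest, the others lying between 0.15 and 0.32 for interferon and between 0.06 and 0.56 for MHC class II. Each of the others turns the sign of the difference between the arms on 1 day. Both lists were already known to be higher in PhIP/DSS on each day, so this order was given beforehand and is no evidence against chance. For gene counts, 4 of the 10 splits, the real one included, gave as many genes at an unadjusted p under 0.05 as the real 442, the highest other being 1397, and 2 of the 4 day-matched splits did. The split with 1397, DSS day 1 with PhIP/DSS days 3 and 7 against the rest, called 233 genes at an adjusted p under 0.05. It is the difference between the arms with the sign of day 1 turned. Across genes that of day 1 was already known to correlate at -0.63 with day 3 and at -0.30 with day 7. The higher counts of this split restate that opposite direction and add no evidence.

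Transcripts of fat cells were noticed in the control and PhIP/DSS day 1 libraries. The adipokine genes Cfd and Adipoq were at 8.45 and 1.48 RPKM in the control and at 55.2 and 6.94 in PhIP/DSS day 1, against at most 0.385 and 0.193 in the other 5 libraries. Of 14 further adipocyte markers with over 10 reads, listed before they were looked at, 8 were higher in both libraries than in each of the other 5, where chance gives 4.76% per gene, among them Thrsp (1.49 and 6.35 RPKM against at most 0.115) and Retn (0.802 and 3.19 against at most 0.188). Exceptions included Lpl and Cidec, and 5 of the 14 reached 1 RPKM in the other libraries. For Plin4, Slc36a2 and Adrb3, counted among the 8, the control stood barely above the highest other library. The values were 0.0907 against 0.0825, 0.215 against 0.196 and 0.0467 against 0.0433 RPKM, gaps that the control's lower depth gives at equal reads. Without these genes the count falls below the share set beforehand for fat tissue carried along. Fat tissue carried along with the scraped epithelium is a candidate source, and whether it also bears on other genes high in PhIP/DSS day 1 was not tested.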
